A study of Arabidopsis thaliana with 8 samples.

How the data were processed

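RNA from whole shoots of Arabidopsis thaliana was measured on 8 ATH1 arrays, 1 array for each of 7 spike mixes and 1 for a reference spike mix, with biotin as the label. The deposited table holds an intensity for each of 22810 probe sets on each array, made with MAS5 per the submitters' processing notes; its version is not given in the sources used here, and neither is a scanner. The values are linear, and their 2% trimmed mean was 100.0 on every array, so they were used as deposited with no further scaling. No array-level replicates exist within a mix, and the number of arrays limits the precision of every value. The labels name the mixes by number and give no amounts of added RNA, so no amounts are used here.

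Probe sets were named through the platform's gene table and a gene table of the TAIR10.1 assembly. Of the probe sets, 13513 had 1 gene, 503 had several and 8794 are unnamed here; 13436 of those with 1 gene were matched in the TAIR10.1 table. A probe set with several genes is given by its identifier. The 64 control probe sets of the manufacturer were kept apart.

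Values below the table's 25th percentile, 12.9, were set to that floor before log2 was taken. A wide-range probe set spanned at least 16-fold over the 8 arrays. Pairs of wide-range probe sets with Pearson r of at least 0.9 over the arrays were counted beside 10000 draws that shuffled the arrays within each probe set. The other probe sets are called native, 22731 in number. For each mix, native probe sets at least 2-fold from the reference array were counted among the 11352 with a mean signal at or above the table's median, 42.5. The SD of log2 signal over the 8 arrays was taken for every native probe set. For gene lists with at least 3 measured members, the median log2 ratio to the reference array was given with its percentile among 10000 random lists of the same size matched on mean signal in 20 bins. These percentiles describe the arrays and are not p-values; no p-value across genes was computed. List medians over the arrays were related to the mean log2 3'/5' ratio of the actin, GAPDH and ubiquitin controls by Pearson and Spearman correlation, with two-sided exact permutation p over 40320 pairings and Benjamini-Hochberg adjustment.

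The named genes followed a rule. All wide-range probe sets, up to 30, were named. For each mix, so were the 3 counted native probe sets with the largest absolute log2 ratio to the reference array. In each list, the 2 members with the highest mean and the 2 with the largest SD were named. These choices, 18 gene lists and most alternatives were fixed before the data were examined. Few members of those lists could be named, and 10 of them had 3 or more; 13 gene families taken by symbol were therefore added after the tables were seen and before their values were. The alternatives were scaling to a common median, quantile normalization, floors at the 10th and 40th percentiles, other thresholds, all native probe sets, the mean of the other 7 arrays as comparator and leaving out arrays.

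The steps were tested on simulated data built on the real mean signals of 22731 probe sets. Of 50 probe sets changed 16-fold, 88% passed the 16-fold range, as did 100% of those changed 32-fold and 0% of those changed 4-fold. For the 2-fold count over 11366 probe sets, 44% of those changed 2-fold in 1 mix were counted, and 100% of those changed 3-fold. Lists of 10 shifted by 0.3 on the log2 scale lay above the central 95% in 98% of 50 draws, and unshifted lists lay outside it in 6%. The simulated noise was independent between probe sets, and the changed probe sets and the lists were all drawn from bright probe sets. The shares recovered therefore do not describe changes in probe sets that start under the floor, where most wide-range ones lay in some mix. The 98% and 6% therefore do not describe shorter or dimmer lists, or lists whose genes move together on an array. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.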

Results

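Gene expression was measured in whole shoots of Arabidopsis thaliana at the stage of 4 rosette leaves, grown on agar plates under a 16 h photoperiod and harvested 6 h into the day. Each of 7 spike mixes and a reference spike mix was measured on 1 ATH1 array, so no value has a replicate of its own mix. A spike mix is a set of RNAs added to the sample. Per array, between 73.6% and 77.0% of the 22810 probe sets lay above the floor of 12.9. Over the native probe sets of the upper signal range, the Pearson r between arrays, taken across genes, which are not independent replicates, ran from 0.976 to 0.992 in 28 pairs.

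The series sets array platforms side by side, and the comparison among mixes shows which probe sets differed between samples that carry different spike mixes. In all, 15 probe sets spanned at least 16-fold over the 8 arrays, and 9 of them had a named gene. The labels do not name the added RNAs, so which RNA each of these probe sets detected is not settled here. The 15 include LEA4-5, a late embryogenesis abundant protein gene, together with AT1G48580, AT3G17520, AT3G19920, AT3G49960, AT1G52560, AT1G02360, AT4G37900 and AT5G66230. Each mix was the highest of the 7 for 2 of these probe sets, except mix 2 with 3. In 13 of the 15 the signal was at or under the floor in at least 1 mix, so their folds, taken against the floor, are lower bounds. AT1G48580 spanned at least 342-fold, with a signal of 4415 in mix 1 and under the floor in mix 3. LEA4-5 spanned at least 304-fold, with 3928 in mix 7 and under the floor in mix 1.

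AT3G17520 was highest in mix 5 at 4117 and spanned at least 319-fold. AT3G19920 and AT3G49960 were both highest in mix 4, at 4099 and 3730. AT1G52560 and AT4G37900 were both highest in mix 2, at 3221 and 2398. AT1G02360 was highest in mix 3 at 2953. AT5G66230 was highest in mix 6 at 4158 and kept a signal of 58.2 in mix 7, so its range was 71.4-fold. The unnamed probe set 260391_at had the narrowest range, 24.8-fold, with 1528 in mix 2 and 330 in mix 1. The other 5 unnamed probe sets were 249940_at, 249353_at, 253067_at, 261345_at and 251252_at, with ranges of at least 311-fold, 291-fold, 273-fold, 247-fold and 243-fold.

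For all 15 probe sets, the next highest mix after the peak was the one numbered 1 lower, counting mix 7 as the one before mix 1, and the mix after that was lower by 1 again. For a given peak, 3.33% of orders would place both in this way. From the peak to the next mix the signal fell by a median factor of 1.96, and by a median factor of 5.72 at the following step. The later step was the larger in 14 of the 15 probe sets, and 260391_at was the exception, with factors of 4.64 and 3.71. AT1G52560 fell 1.25-fold and then 6.09-fold, while AT4G37900, with the same peak, fell 2.09-fold and then 11.8-fold. On the reference array every one of the 15 lay within 2-fold of its signal in the mix numbered 2 below its peak, and between 4.22% and 15.8% of its peak signal. The labels give the same shoots for every mix. An order by mix number in all 15 argues against shoot transcripts alone as the source of these differences.

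**Figure D1:**
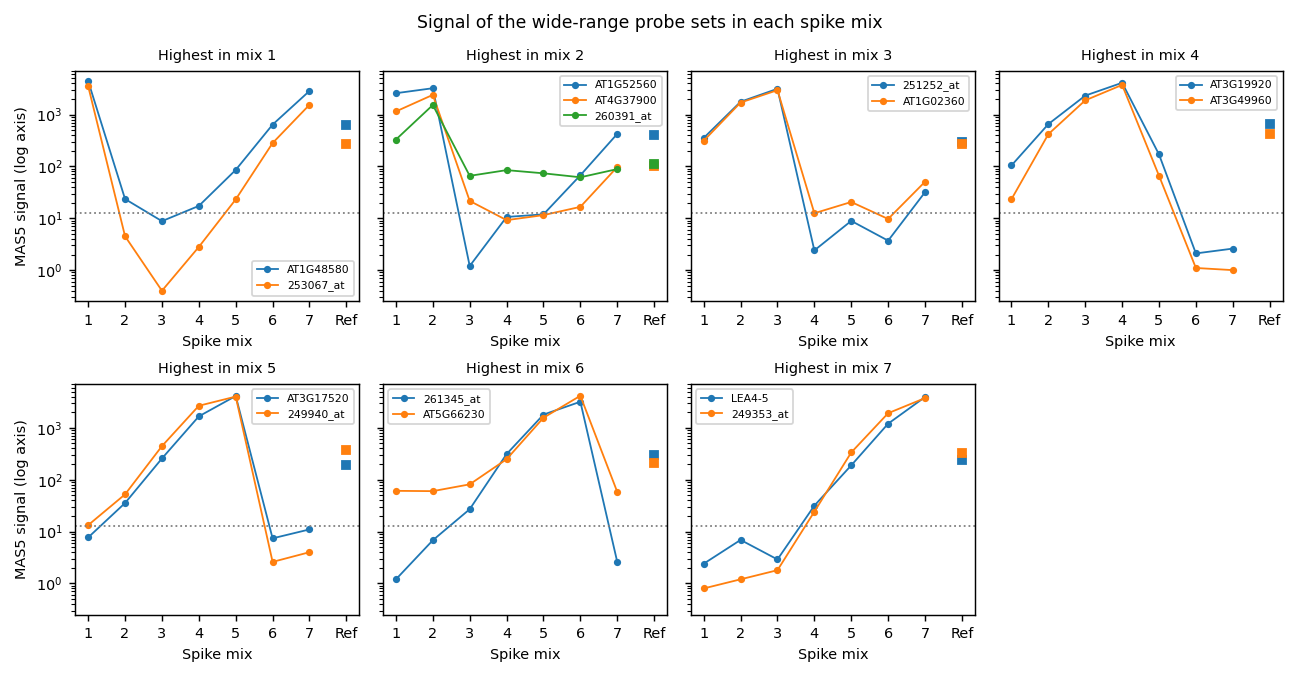
MAS5 signal on a log axis of the 15 wide-range probe sets in spike mixes 1 to 7 (points joined by lines) and on the reference array (squares), 1 panel per mix with the highest signal; the dotted line is the floor of 12.9. In each panel the signal falls from the peak over the next 2 lower mix numbers, with mix 7 following mix 1.

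Probe sets with the same peak mix shared their profile over the arrays. Of 105 pairs, 8 had r of at least 0.9, and all 8 had the same peak mix. AT3G19920 and AT3G49960 had r = 0.972 over the 8 arrays, and LEA4-5 and 249353_at had r = 0.994. AT1G52560 and 260391_at were the only pair with the same peak mix below that threshold, at r = 0.791. With the arrays shuffled within each probe set, the highest count in 10000 draws was 4.

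Outside these 15, most probe sets differed little between mixes, and 24 native ones spanned from 4-fold to under 16-fold. The widest range after the floor was that of 263216_s_at, which is assigned to several genes. It spanned at least 8.34-fold, with 108 in mix 7, then 23.8 in mix 6 and 17.1 in mix 4. Among 11352 native probe sets, those at least 2-fold higher than on the reference array numbered 13, 11, 10, 19, 13, 34 and 13 in mixes 1 to 7. Those at least 2-fold lower numbered 7, 0, 4, 14, 5, 30 and 13. With arrays scaled to a common median the balance turned in mix 4, to 11 higher and 25 lower, and in mix 6, to 20 and 52. All 7 comparisons share the 1 reference array. AT5G51840 and 253947_at were at least 2-fold higher in every mix, and AT5G51840 had a signal of 14.1 on the reference array and of 42.8 to 50.5 in the mixes. Against the mean of the other 7 arrays those higher numbered 3, 0, 1, 2, 0, 2 and 1 and those lower 5, 1, 2, 10, 3, 14 and 5, so that more were lower than higher in every mix.

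AT1G63310 was 3.74-fold higher in mix 1, at a signal of 107 against 28.7 on the reference array. AT1G26740 had a log2 ratio of -2.04 in mix 4, a bound, since it was under the floor there. AT4G32605 had log2 ratios of -1.92 in mix 3 and -2.12 in mix 6, and its signal was also low in mix 7, at 26.1 against 84.2 on the reference array. AT5G66290 had log2 ratios of -1.45 in mix 3 and -1.71 in mix 4. AT2G25190 had a log2 ratio of -1.86 in mix 5, and AT1G13730 of -2.10 in mix 6. AT2G25190 was also low in mix 4, at 27.8 against 66.4 on the reference array. AT1G13730 was also low in mix 1, at 24.8 against 66.5. The unnamed probe set 259954_at had a log2 ratio of -2.54 in mix 7 and lay under the floor in mix 6, where -2.55 is a bound. Its signal was highest on the reference array, and against the mean of the other 7 arrays these were -1.71 and -1.72. The unnamed 257954_at had a log2 ratio of 1.44 in mix 1 and 260078_at of 1.26 in mix 2; both were lowest on the reference array, and against the mean of the other 7 arrays these were 0.55 and 0.77. On that comparison AT4G32605 had -1.16 in mix 3 and -1.39 in mix 6, and AT5G51840 between 0.09 and 0.36 in the mixes where it is named. Each of these probe sets had a mean signal under 99.

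The median SD of log2 signal over the 8 arrays was 0.15 for native probe sets and 3.30 for the 15 wide-range ones. With native probe sets split into 4 equal bins of mean signal, it was 0.29 in the bin from 13.1 to 42.4, 0.17 in the next and 0.12 in the brightest; most of the dimmest bin lay at the floor. Without the arrays of mixes 4, 5 and 6 the native median was 0.12.

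Genes of the photosystems and the Calvin cycle were lower in mixes 2 and 3 than on the reference array. Over both mixes, the 221 other brightest probe sets were lower too as a set, with a median log2 ratio of -0.13. All 5 measured members of the photosystem and Calvin cycle list were lower in both, with a median log2 ratio of -0.20 in mix 2, at percentile 1.70 of random lists, and -0.32 in mix 3, at percentile 0.010. After quantile normalization these medians were -0.11, at percentile 9.57, and -0.23, at percentile 0.050. RCA, which encodes Rubisco activase, had log2 ratios of -0.20 and -0.39, and PSAE-1, a subunit of photosystem I, -0.32 and -0.52. The 3 light-harvesting genes had medians of -0.22 in mix 2, at percentile 3.2, and -0.18 in mix 3, at percentile 11; after quantile normalization both turned, to 0.048 and 0.0044, and against the mean of the other 7 arrays the median in mix 3 was -0.23 at percentile 1.31. LHCB4.1, an antenna protein of photosystem II, had -0.22 and -0.21, and LHCB4.2 had -0.11 and -0.18. In mix 4 the photosystem list had a median of 0.10 at percentile 98; after quantile normalization it was 0.011 at percentile 64.7, and under scaling to a common median, which shifts all genes alike, -0.016 at percentile 98. Among lists matched on the 100 nearest mean signals, the photosystem list lay at percentile 11.7 in mix 2, 0.25 in mix 3 and 91.5 in mix 4.

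Genes encoded in the chloroplast genome were higher than on the reference array in mixes 1, 2, 3 and 7, relative to random lists. In mix 7, 56 of the 69 measured genes were higher, with a median log2 ratio of 0.17; in mix 1, 48 were higher, with a median of 0.16. The median was 0.08 in mix 2 and 0.05 in mix 3, and percentile 100 was reached in mixes 1, 2, 3 and 7. The size depended on the setting: in mix 1 the median was 0.09 after quantile normalization, in mix 2 it was 0.04 under scaling to a common median, and against the mean of the other 7 arrays it was 0.03 in mix 2 and 0.02 in mix 3. Scaling to a common median, which shifts all genes alike, turned the median in mix 3 to -0.018 and left it at percentile 100. In mix 5 the median of 0.02 lay at percentile 98.2, but at percentile 51.6 after quantile normalization, and against the mean of the other 7 arrays it turned to -0.037 at percentile 0.14. On that last comparison the median in mix 4 was -0.11, at percentile 0. The arrays of mixes 4, 5 and 6 stood apart in the first principal component of the native probe sets, which held 29.1% of the variance, with loadings of 0.57, 0.34 and 0.38 against -0.34, -0.40, -0.33 and -0.16 for mixes 1, 2, 3 and 7; the chloroplast list's level was -0.10, -0.03 and 0.0076 on those 3 arrays. The members went both ways: rps18, a plastid ribosomal protein gene, had log2 ratios of 0.70 in mix 1 and -0.25 in mix 4, ndhF had 1.07 in mix 3 and -0.53 in mix 4, and the ATP synthase genes atpB and atpE had -0.18 and -0.17 in mix 2.

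**Figure D2:**
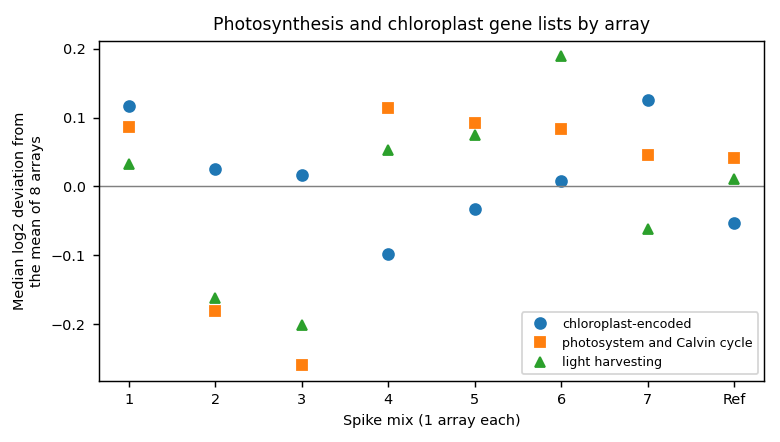
Median log2 deviation of 3 gene lists from each member's mean over the 8 arrays, 1 point per list and array. The photosystem and Calvin cycle list is lowest in mix 3 at -0.26, and the chloroplast-encoded list is highest in mix 7 at 0.12.

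Among the other lists, 3 more values lay outside the central 95% of random lists. Defence genes had a median log2 ratio of 0.70 in mix 5 with 2 of 3 members higher, at percentile 98.6. That median is the ratio of PDF1.2b, a defensin gene, whose reference signal of 11.6 lay under the floor, so it is a bound. THI2.1, a thionin gene, had 1.06 with a reference signal of 13.1, and also 0.96 in mix 6 and 1.04 in mix 7. With the floor at the 40th percentile the list's median in mix 5 was 0.00. Flavonoid genes had 0.43 in mix 3 with 3 of 4 members higher, at percentile 98.6, with DFR at 0.35 and UGT78D2 at -0.24; with the floor at the 40th percentile the median was 0.18 at percentile 93.4, and against the mean of the other 7 arrays 0.24 at percentile 97.2. Reference genes had -0.20 in mix 3 with 3 of 5 members lower and 2 higher, at percentile 2.23, with GAPC2 at -0.23, TUB6 at -0.20, AT4G34270 at -0.34 and PEX4 at 0.00; against the mean of the other 7 arrays the median was -0.09 at percentile 11.6, and after quantile normalization it lay at percentile 5.24. Of 70 pairs of a list and a mix, 11 lay outside the central 95%, and the alternatives gave 8 to 13. Chance would give 3.5 if the pairs were independent and all medians could move. They were not independent, since the mixes share 1 reference array and several of the 11 belong to the chloroplast list. The floor also held some medians at 0, such as that of defence genes in mix 2. No excess over chance can therefore be read from the count.

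Genes of cold and drought response, cytosolic ribosomal proteins, heat shock and root markers had no median outside the central 95% in any mix against the reference array. Against the mean of the other 7 arrays, cold and drought genes had 0.20 in mix 1, at percentile 98.6, and heat shock genes -0.30 in mix 7, at percentile 2.07. COR47 and COR15A, both induced by cold, had mean signals of 875 ± 61.5 and 567 ± 29.0 (SD, n = 8 arrays), and COR15B 542 ± 72.6. The ribosomal protein genes AT5G02870 and AT3G09630 had 1295 ± 110 and 1042 ± 73.5. The small heat shock gene ATHSP22.0 had 28.2 ± 8.90. Among root markers, PYK10, a beta-glucosidase of endoplasmic reticulum bodies, had 999 ± 76.1, while the root hair expansins EXPA7 and EXPA18 had 21.0 ± 3.98 and 24.6 ± 5.49. Lists with 1 measured member gave 189 ± 15.9 for the clock gene GI, 110 ± 12.1 for the mitotic kinase gene AUR1, 72.4 ± 13.2 for SAG29 and 21.9 ± 6.85 for STZ; the flower marker AT5G07230 lay under the floor on all 8 arrays. Seed storage and nitrate genes had no named probe set.

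The hybridisation controls, which are added after labelling, were higher on some arrays than others. Their 18 probe sets were 1.90-fold, 1.69-fold and 1.46-fold above the reference array in mixes 1, 6 and 7, and between 1.01-fold and 1.19-fold in the other mixes. The 25S rRNA control had a signal of 2198 in mix 1, 272 in mix 6 and 847 on the reference array. The 27 poly(A) control probe sets reached at most 25.5. The 3'/5' ratio was between 1.80 and 2.17 for actin, 1.03 and 1.24 for GAPDH and 1.57 and 1.84 for ubiquitin. Over the 8 arrays, none of 10 relations of a list median to the mean 3'/5' ratio stood out after adjustment, but 8 arrays cannot exclude one. Spearman rho was -0.60 (exact permutation p = 0.132) for the chloroplast list and 0.57 (exact permutation p = 0.151) for the photosystem list. The root marker list had the largest r, 0.69, with two-sided exact permutation p = 0.0629 and adjusted p = 0.629, and Spearman rho 0.57 with exact p = 0.151 and adjusted p = 0.504; without the 2 arrays farthest from the median ratio r was 0.76.

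**Figure D3:**
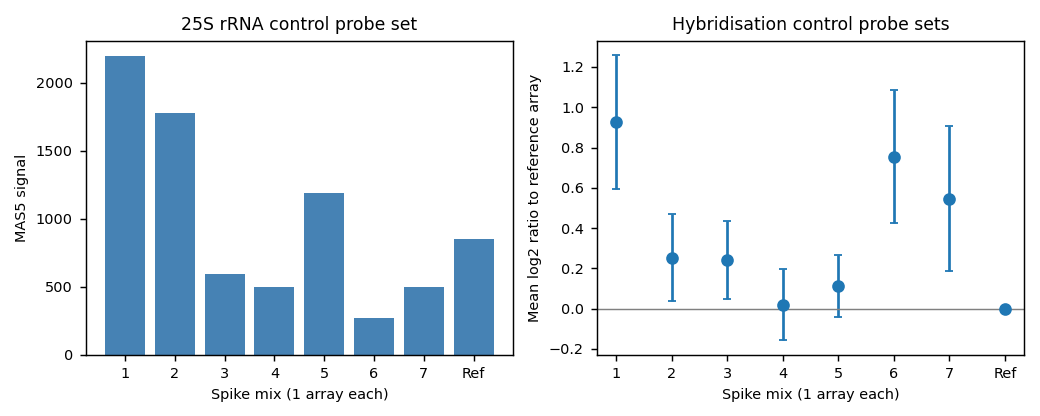
Left, MAS5 signal of the 25S rRNA control on each array; right, mean log2 ratio to the reference array of 18 hybridisation control probe sets, with bars of 1 SD over probe sets. Mixes 1, 6 and 7 have the highest hybridisation controls.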

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

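Of the tests weighed here, those on cross-hybridisation, equally bright or brightest probe sets, RNA without poly(A) tails and the reference array were chosen after the result was seen; the count of followers was set down before it was computed.

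Outside the 14 widest probe sets, 260391_at moved with the probe sets that peak in mix 2. Its signal in mix 2 was 20.8-fold the median of its own 5 lowest mixes; cross-hybridisation of an added RNA may account for this, but so could an added RNA of its own, and these cannot be told apart without probe sequences. Of 2077 other probe sets with a range of at least 2-fold, 8 had r of at least 0.95 with a mean profile of the 14 by peak mix, and 3.30% of 1000 shuffles of the arrays gave as many, so chance resemblance is not excluded for these. No biological explanation was tested.

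The lower signal of photosynthesis genes in mixes 2 and 3 may reflect a loss shared by the brightest probe sets. Over both mixes, the 8 listed probe sets had a median log2 ratio of -0.21, and the 221 other brightest probe sets -0.13. Against lists matched on the 100 nearest mean signals, the 8 lay at percentile 4.24, inside the central 95%; the photosystem list lay at 11.7 in mix 2 and 0.25 in mix 3, and the light-harvesting list at 10.2 and 25.7; quantile normalization, which removes such a loss, turned the light-harvesting medians and left the photosystem list in mix 3 at -0.23. The highest signal on the array was 3741 in mix 2 and 3748 in mix 3, and from 4606 to 5230 on the other arrays. Only 5 of the 31 genes of the photosystem list and 3 of the 20 light-harvesting genes could be measured. Members without a named probe set may therefore be among the probe sets used for comparison. A shared loss and a loss in these genes cannot be told apart from these values. No biological explanation was tested, since the labels give the same shoots for every mix.

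Relative to random lists, chloroplast-encoded genes were higher in mixes 1, 2, 3 and 7, and this was not a shift of equally bright probe sets, since all 4 mixes lay at percentile 100 among lists matched on the 100 nearest mean signals. A low reference array alone did not account for mixes 1 and 7: against the other 6 mixes their medians were 0.14 and 0.12. In mixes 2 and 3 the medians against the other 6 mixes were only 0.012 and 0.013, at percentiles 99.7 and 99.98, with mixes 4 and 5 at -0.12 and -0.06, so a low reference array may account for much of those 2 shifts and stays open. Carry-over of RNA without poly(A) tails could raise these genes, but the relation of their median to the 25S rRNA control had r = 0.25 (exact permutation p = 0.542) and Spearman rho 0.17 (exact permutation p = 0.703) over the 8 arrays, and r = -0.07 without the 2 farthest arrays, so this stays open. No biological explanation was tested.

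Of 124 measures taken over the 8 arrays, 16 had 1 array far from the other 7. Chance gives about 1 in 20 for measures not chosen for their spread, but many of these were named for a large ratio or SD, so no excess over chance can be read from the count. AT1G63310 stood at 107 in mix 1. AT5G51840 and 253947_at stood low on the reference array, at 14.1 and 21.3. AT1G26740 stood at 11 in mix 4, and PEX4 at 201 in the same mix. UGT85A7 stood at 28.2 and TET5 at 21.4 in mix 1. TET7 stood at 196 and GSTU18 at 207 in mix 6. As median log2 deviations, defence genes stood at 0.44 in mix 5, cold and drought genes at 0.18 and tetraspanins at -0.16 in mix 1, and xyloglucan endotransglucosylases at 0.12 in mix 5. The remaining 3 were list medians that barely moved on any array, with deviations of -0.0035 for cytochrome P450 and 0.0061 for beta-glucosidases in mix 6 and -0.014 for tau glutathione transferases in mix 5.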

How the results depend on the processing

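The nearest-signal matching, the set without 260391_at, the comparator without mix 6 and the set without mixes 4, 5 and 6 were chosen after seeing the data. The count of 15 wide-range probe sets ran from 14 to 18 under its alternatives (14 to 15 with an array left out), and the 8 pairs from 6 to 9. After scaling to a common median, the median log2 ratio of native probe sets was -0.11 in mixes 4 and 6. It gave 11 higher and 25 lower in mix 4, 20 and 52 in mix 6, 10 and 8 in mix 5, and 9 and 2 in mix 2; quantile normalization gave 13 and 23 in mix 4, 24 and 42 in mix 6 and 12 and 8 in mix 5. At 3-fold the counts in mixes 1 to 7 were 2, 1, 2, 5, 2, 8 and 4, by construction fewer, with 1 higher and 7 lower in mix 6. With all native probe sets they were 142, 85, 111, 343, 242, 441 and 173, with 260 higher and 83 lower in mix 4 and 323 and 118 in mix 6. Against the mean of the other 7 arrays they were 8, 1, 3, 12, 3, 16 and 6, and without mix 6 in that mean 8, 0, 2, 11, 2 and 8 in mixes 1 to 5 and 7; the cause was not tested. The median SD was 0.21 with the floor at the 10th percentile, 0.10 at the 40th and 0.12 without mixes 4, 5 and 6; with 1 array left out it ran from 0.14 to 0.15, lowest without mix 6. Under median scaling the chloroplast median turned to -0.018 in mix 3 and -0.055 in mix 5, and the photosystem median in mix 4 to -0.016. This scaling shifts all probe sets alike, and the percentiles stayed at 100, 98.1 and 97.515. In mix 5 the chloroplast median was -0.0064 after quantile normalization, at percentile 51.6, and -0.037 against the other 7 arrays, at percentile 0.14; the cause was not tested. The count of 11 planned list values outside the central 95% ran from 8 to 13. None of the 105 alternative values of the named native ratios changed sign. These ratios were chosen as the largest per mix, so a change of sign was unlikely from the start. Their size could still fall: AT5G51840 in mix 1 went from 1.60 to 0.09 against the mean of the other 7 arrays. No paired analysis was possible because each mix has 1 array and the mixes share only replicate number 1. Signals near the floor of 12.9 limit what can be read from dim genes.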

Other observations

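Among the gene families added by symbol, sugar transporters included SWEET11, with a mean signal of 770 ± 91.7 (SD, n = 8 arrays), and glutathione transferases of the tau class GSTU20, with 1065 ± 74.5. Expansins included EXPA8, with 917 ± 24.8, glycosyltransferases UGT88A1, with 831 ± 32.8, and ubiquitin-conjugating enzymes UBC28, with 1461 ± 93.1. Carboxypeptidase-like SCPL49 had 399 ± 24.2, TBL25 491 ± 51.5, BGLU44 488 ± 52.1, TET8 324 ± 42.7, CYP71B26 285 ± 33.9, XTH32 256 ± 13.9, AGL26 201 ± 19.9 and mitochondrial nad4 313 ± 33.6.

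Of 91 pairs of an added family and a mix, 5 lay outside the central 95% of random lists; lists with most members at the floor could not fall outside it, so no chance count is set beside this. Expansins had median log2 ratios of -0.14 in mix 2 and -0.08 in mix 3. The ubiquitin list had -0.09 in mix 2, the trichome birefringence-like list -0.09 in mix 7 and the xyloglucan endotransglucosylases 0.19 in mix 5. Against the mean of the other 7 arrays the last of these stayed outside the central 95%, at percentile 98.01, and the other 4 did not; with the floor at the 40th percentile its median was 0.00, as were those of the trichome birefringence-like list in mix 7 and of expansins in mix 3, and expansins had -0.015 in mix 2. For the MADS box list in every mix, and for beta-glucosidases in mix 3, the floor fixed the median at 0, so these could not be tested. The glycosyltransferase, cytochrome P450 and carboxypeptidase-like medians were also 0 in every mix. Many of their members had a ratio of 0 after the floor, so these medians are weak evidence of no shift. The glycosyltransferase, cytochrome P450, carboxypeptidase-like and tetraspanin lists had no median outside the central 95% against the reference array. Nor did the sugar transporter, glutathione transferase and mitochondrial lists, or beta-glucosidases in the other mixes. Against the mean of the other 7 arrays, sugar transporters had -0.23 in mix 2, at percentile 0.28, 0.22 in mix 4, at percentile 98.1, and 0.30 in mix 6, at percentile 99.3, and tetraspanins had -0.18 in mix 1, at percentile 0.53, and 0.05 in mix 2, at percentile 97.9.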
